A study of Mus musculus with 10 samples.

How the data were processed

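The study hybridised biotinylated cRNA, made with a commercial amplification kit per the labels' protocols, to Illumina mouse bead arrays with 45281 probes. The tissue was laser-microdissected SVZ from 4 Tlx overexpressing and 5 wild type BL6 mice, and every mouse had a stroke. Labels name the genotype and a mouse number for each of the 10 arrays. In the order used here, Tlx overexpressing replicates 1 to 4 were mice 2995, 3155, 3157 and 3163, and wild type replicates 1 to 5 were mice c1, c2, 2989, 2996 and 3164. The labels' mouse names fall in 3 ranges: 2995, 2989 and 2996, then 3155, 3157, 3163 and 3164, then c1 and c2. They do not say what a range stands for, nor which hemisphere was captured or how long after the stroke.

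The authors deposited 2 tables of probe intensity on a linear scale. In the table called non-normalized, the columns had quartiles equal within 0.01 (36.02 to 36.03 and 85.66), medians of 40.69 to 40.71 and 1 maximum, so it held values already quantile-normalized between arrays. In the other deposited table, the intensity columns had medians of 36.8 to 43.2 and different maxima, and each had the same probe ranks as its partner (Spearman's rho of 1), so it held signals before normalization between arrays. What background treatment or software the authors used before deposit is not given in the sources used here. A detection p-value per probe and array was deposited beside the quantile-normalized intensities, per the file headers. The headers do not define it, and it was taken here as the share of negative controls at or above the probe's signal. The signals before normalization were taken as the starting values and the quantile-normalized ones as an alternative, the reverse of the plan, which had assumed the table's name to be right.

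Signals were corrected with normexp against negative controls inferred from the detection p-values, with an offset of 16, quantile-normalized and put on the log2 scale (neqc method, limma 3.58.1 in R 4.3.3). The 2 arrays of c1 were averaged after normalization and counted as 1 mouse. Probes were kept where the detection p-value was under 0.05 in at least 4 of 9 mice, which left 20401. The signals are relative brightness: levels of different probes are not comparable, and small changes of dim probes are compressed by the offset. Probe names came from the platform's annotation, in which 34885 probes had 1 gene symbol, 18 several and 10378 none. Symbols were updated through the RefSeq table of assembly GRCm38.p6, which matched 34807 probes, and no coordinates were taken from it. Probes with several genes were left unnamed. A gene with several probes is described by the probe the rule below selected, or in lists by its brightest probe. Other probes of called genes are given where they did not pass or had the other sign.

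Genotypes were compared with lmFit and eBayes of limma, two-sided, with Benjamini-Hochberg adjustment over all tested probes, at a threshold of 0.05. Every adjusted p of a gene is from this model. The fold changes are differences of mean log2 signals. Nr2e1 also had an exact two-sided permutation test over all ways to choose 4 of the 9 mice. Of 31 gene lists written from textbook knowledge before the data were examined, 30 were tested and 1, sex markers, served as a check. List tests used camera with a preset inter-gene correlation of 0.01, adjusted over 30 lists, and again with an estimated correlation. A list level per mouse is the mean over its genes of the log2 signal centred over the 9 mice, tested by exact permutation. The mean level of 3 lists was also fitted by a linear model with genotype and the range of the mouse number. Several lists share genes, among them Sox4, Dlx1, Gfap and Vim, and the list of reported Tlx-repressed genes holds only Cdkn1a, Bmp4, Gfap and Aqp4 among the probes tested.

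The genes named in the text were chosen by a rule fixed before the data were examined. It took Nr2e1 and the 12 highest and 12 lowest log2 changes among named probes past the threshold that separated every mouse of the 2 genotypes, skipping unnamed clones. From every list it took the members past the threshold, or else up to 4 with the smallest p. Genes outside this rule are said to be chosen after their values were seen, or, in lists, are given to show members that did not pass over all probes.

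The procedure was tested on simulated arrays with the same group sizes, 200 changed probes and normal noise with each probe's SD between the real mice. The filter kept 23999 simulated probes. Of changed probes, 2.08% were called at 1.3-fold, 44.9% at 1.5-fold, 84% at 2-fold and 85.7% at 3-fold, with median estimated folds of 1.30, 1.48, 1.93 and 2.94. Of 23773 unchanged probes 8 were called. A list raised by 0.3 was estimated at 0.32, and 0 of 29 unchanged lists were called. Simulated genes varied independently, so this test says nothing about lists whose genes vary together between mice.

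Alternatives set before the data were examined were other background correction, scaling, sources of values, filters, arrays of c1, array weights, a trended prior, thresholds, a block for the range of the mouse number, list tests, leaving out mice c1 and c2 and leaving out each mouse. Added after the data were seen were leaving out mice 2989 and 2996, leaving out mice 3155 and c1, and the choroid plexus list level as a covariate. The files name no slide, so a slide block was not run. A probe of the Y-linked gene Eif2s3y was detected in all 9 mice, at log2 signals of 4.56 to 5.1, close to background. Its other probe was detected in 7 mice, 1 Uty probe in 8, and the other Uty and both Kdm5d probes in 0. Xist was above background on 1 of its 4 probes in 1 mouse. These markers showed no clear difference in sex but were too dim to settle it, so a sex covariate was not run.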

Results

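Gene expression was measured in the subventricular zone (SVZ), the layer along the lateral ventricle where new neurons are made in the adult mouse brain. The tissue was taken by laser microdissection from BL6 mice 8 weeks old, all of which had received an ischemic stroke in the striatum of 1 hemisphere. The labels give 4 mice overexpressing Tlx, the nuclear receptor encoded by Nr2e1 that keeps neural stem cells undifferentiated, and 5 wild type mice. The comparison asked what Tlx overexpression did to gene expression in the SVZ after stroke. Wild type mouse c1 was hybridised to 2 arrays, so 10 arrays gave 9 mice. Each array carried 45281 probes, of which 20068 to 20590 (44.3% to 45.5%) were detected above the negative controls, and 20401 probes for 11376 named genes were tested. With 4 and 5 mice, the number of animals limits the precision of every comparison.

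Nr2e1 itself was measured by 1 probe, ILMN_2689177, close to background. Its log2 signal was 5.43 ± 0.14 (SD, n = 4) in the Tlx overexpressing mice and 5.01 ± 0.19 (SD, n = 5) in wild type mice, a difference of 0.41 (SE 0.11) or 1.33-fold. All 4 Tlx overexpressing mice (5.27 to 5.61) lay above all 5 wild type mice (4.69 to 5.19), and the exact two-sided permutation test of this probe gave p = 0.00794, the smallest that the splits of 9 mice into 4 and 5 allow. In the fit over all probes the difference did not pass the threshold (limma adjusted p = 0.084). It was 0.28 (adjusted p = 0.39) with the range of the mouse number as a block. It was 0.12 among mice 2995, 2989 and 2996 and 0.41 among mice 3155, 3157, 3163 and 3164. A transgene without the native 3′ end of the transcript may go unseen by such a probe, so the value need not measure the transgene.

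Over all tested probes, 192 differed between the genotypes at an adjusted p under 0.05, 110 higher and 82 lower in the Tlx overexpressing mice. They stood for 85 higher and 71 lower genes, with 21 probes that had no gene name. The changes were moderate: the median was 1.54-fold among the higher and 1.53-fold among the lower probes, and the largest were 2.89-fold and 2.24-fold. Among the 12 genes with the highest changes were 4 interferon-stimulated genes, Usp18, Ifit3, Isg15 and Oasl2. Usp18, which removes the ubiquitin-like protein ISG15 from its targets and restrains interferon signalling, rose by 1.53 on the log2 scale (SE 0.25, adjusted p = 0.016), and Ifit3 rose by 1.35 (SE 0.16, adjusted p = 0.0028). The transcription factor Gbx2 rose by 1.49 (SE 0.31, adjusted p = 0.044) and Tfap2c by 1.34 (SE 0.23, adjusted p = 0.024). The other genes of this group were the matricellular protein Ccn5 (1.49), the serotonin receptor Htr5b (1.12), the noncoding transcript Fzd10os (1.05), the chemokine Ccl4 (1.04), complement C4a (1.01) and the neuropeptide galanin, Gal (0.88). Gal was detected in all 4 Tlx overexpressing mice and in 2 of 5 wild type mice, whose mean of 4.45 lay near background, so its change and its place among the 12 are approximate. Other C4a probes read 0.65 and -0.11 and did not pass. C4b, nearly identical in sequence and chosen after its values were seen, had probes at 0.78, 0.81 and 0.27, the last not past the threshold.

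Ednrb and Tnc showed the largest decreases. The endothelin receptor gene Ednrb, expressed by astrocytes and progenitors, had a log2 change of -1.16 (SE 0.10, adjusted p = 0.00099), with 9.33 ± 0.03 (SD, n = 4) against 10.49 ± 0.21 (SD, n = 5). Its other probes had the same sign (-0.76 and -0.63) and did not pass. Tnc, an extracellular matrix protein of the stem cell niche, changed by -1.16 (SE 0.14, adjusted p = 0.0028). The mitochondrial carrier Slc25a18 changed by -0.92 (SE 0.09, adjusted p = 0.0011) and the transcription factor Dmrt3 by -0.91 (SE 0.18, adjusted p = 0.035). The tight junction protein Cldn1 (-1.11), the cadherin Cdh3 (-0.96) and the keratins Krt8 (-0.93) and Krt18 (-0.89) fell as well. The last of the 12 were Calml4 (-1.14), the calcium channel Trpv4 (adjusted p = 0.019), the leukotriene synthase Ltc4s (-0.86) and Mia (-0.85). The other probes of Trpv4 (-0.49 and -0.37) and Cdh3 (-0.39) did not pass. Of the 192 probes, 187 separated every Tlx overexpressing mouse from every wild type mouse, as did 6.28% of all tested probes, where chance gives 1.59%.

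The number of called probes depended strongly on which mice entered. It was 753 without Tlx overexpressing mouse 2995, 71 without 3155, 27 without 3157 and 39 without 3163, and it was 63 without wild type mouse c1, 84 without 2996 and 122 without 3164. It was 51 with the range of the mouse number as a block, 6 with the level of choroid plexus genes as a covariate, 31 without mice 3155 and c1, 378 without mice 2989 and 2996, 98 without mice c1 and c2, 57 with no filter on dim probes and 609 with array weights. Of 40 called probes that the naming rule gave, 14 kept their call with the block: both of Oasl2 and those of Usp18, Ifit3, Isg15, Fzd10os, Ccl4, C4a, Ednrb, Tnc, Slc25a18, Egfr, Igfbpl1 and Acta2. The other 26 lost it, among them Gbx2, Tfap2c, Ccn5, Htr5b, Gal, Dmrt3, Krt8 and Hopx. With the covariate 3 kept it and 37 lost it. Of these 37, 19 had changes within 1.5 times of those without it, or larger, and a larger SE, among them Usp18 (2.05), Ifit3 (1.51), Tnc (-1.32), Slc25a18 (-0.95), Hopx (-0.58) and Dcx (0.55). The other 18, 11 of them lower, shrank more. Among the lower were Cldn1 to -0.34, Cdh3 to -0.54, Krt8 to -0.23, Krt18 to -0.28, Dmrt3 to -0.27, Trpv4 to -0.43, Ltc4s to -0.31 and Mia to -0.40. The 7 higher ones were Ccn5 to 0.58, Gbx2 to 0.93, Tfap2c to 0.795, Htr5b to 0.70, Gal to 0.51, Prokr2 to 0.48 and the neuroblast gene Tubb2b to 0.27. The call of Gbx2 was lost in 15 of 23 alternatives, 7 of which left out 1 mouse and 1 of which used the authors' normalized values, with log2 changes of 0.93 to 1.68 and adjusted p of 0.022 to 0.83. It was not alone: Gal lost its call in 14 of 23, Cldn1 in 13 of 24 and Krt8 and Dmrt3 each in 12 of 24. For Cldn1, Krt8 and Dmrt3, 7 of these left out 1 mouse, and for Gal 6. By contrast, Ifit3, Fzd10os, Ccl4, C4a, Tnc and Slc25a18 lost theirs in 1 of 24.

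**Figure D1:**
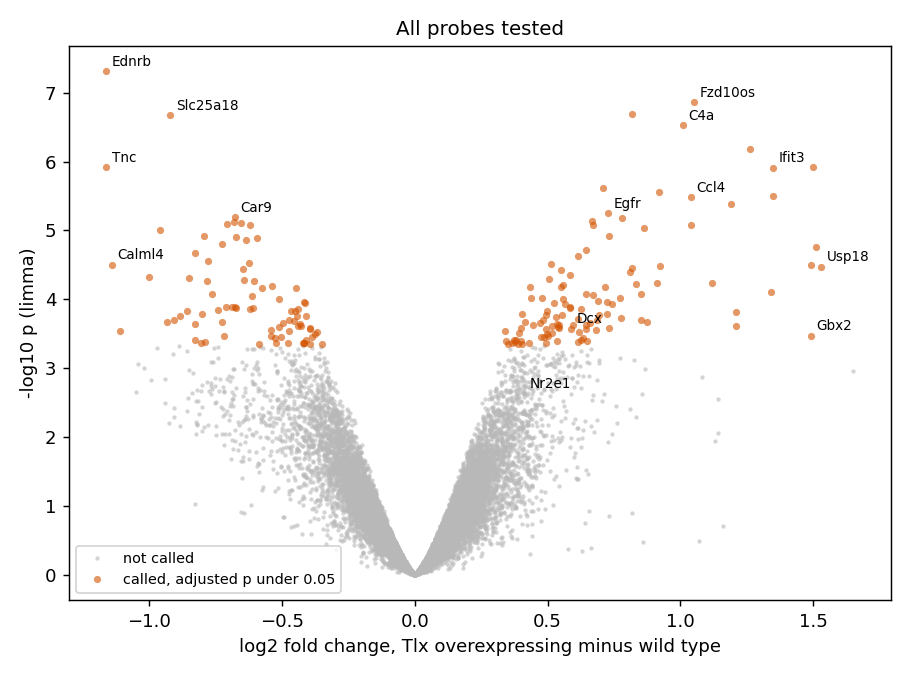
Log2 fold change (horizontal axis, Tlx overexpressing minus wild type) against -log10 of the unadjusted limma p (vertical axis) for 20401 probes; orange points are the 192 probes with an adjusted p under 0.05. Ednrb, Slc25a18 and Tnc stand highest at left with log2 changes of -1.16, -0.92 and -1.16, and Nr2e1 (0.41) lies among the grey points below the threshold.

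Genes of transit-amplifying progenitors, neuroblasts and dividing cells were higher in the Tlx overexpressing mice. All 7 measured genes of the transit-amplifying list had a positive change, with a mean log2 change of 0.37. Egfr, the epidermal growth factor receptor carried by these progenitors, rose by 0.73 (SE 0.10, adjusted p = 0.007), from 8.69 to 9.42, and Sox4 rose by 0.57 (SE 0.10, adjusted p = 0.029), although a dimmer Sox4 probe read 0.08 and did not pass. Only 1 of 5 Egfr probes passed, and all 5 were positive. Dlx1 (0.45, adjusted p = 0.064) and the brightest probe of Ccnd2 (0.37, adjusted p = 0.14) did not pass, although another Ccnd2 probe did (0.67, adjusted p = 0.026). In the neuroblast list, 16 of 18 measured genes were positive, with a mean of 0.26. Dcx, the microtubule protein of migrating neuroblasts, rose by 0.59 on the log2 scale (SE 0.12, adjusted p = 0.038). Igfbpl1 rose by 0.72 (SE 0.14, adjusted p = 0.033), Tubb2b by 0.44 (SE 0.09, adjusted p = 0.037), and Sox4 counted here too. Further probes of Dcx (0.27), Tubb2b and Igfbpl1 were positive, and all but 1 of them, for Igfbpl1, did not pass. In the cell cycle list, 28 of 29 measured genes were positive, with a mean of 0.36. Cdca3 (0.65, adjusted p = 0.037) and Cenpa (0.63, adjusted p = 0.047) rose, whereas Aurka (0.60, adjusted p = 0.064), Bub1b (0.52, adjusted p = 0.076) and Top2a (0.50, adjusted p = 0.12) did not pass.

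Adjusted over the list alone, 4 of 7 transit-amplifying, 8 of 18 neuroblast and 19 of 29 cell cycle genes rose. The lists were called by camera with a preset correlation of 0.01 (adjusted p = 2.9e-05, 4.9e-06 and 7.2e-14). With an estimated correlation none of the 3 was called (adjusted p = 0.29 for each). As exact permutation tests of the list level per mouse, the lists gave p = 0.016, 0.016 and 0.024, or 0.095, 0.095 and 0.12 after adjustment over 30 lists. The mean difference of the 3 lists was 0.21 among mice 2995, 2989 and 2996 and 0.45 among mice 3155, 3157, 3163 and 3164, and it was 0.34 (SE 0.077) with the range as a block. The cell cycle list alone differed by 0.14 and 0.52 in these ranges, and its level in Tlx overexpressing mouse 2995 (-0.03) lay below that of wild type mouse c2 (0.06). The calls of Dcx, Igfbpl1, Sox4 and Tubb2b were each lost on leaving out any 1 of mice 3155, 3157, 3163, c1 or 2996, with log2 changes between 0.53 and 0.70 for Dcx over all settings and adjusted p between 0.0079 and 0.76. Cdca3 lost its call in 13 and Cenpa in 16 of 24 alternatives, each on leaving out any 1 of 7 mice, all but 2995 and c2, and with the block. With the choroid plexus level as a covariate the 3 lists stayed called but shifted less, by 0.28, 0.19 and 0.26. Their camera adjusted p with the preset correlation was then 0.0028, 0.0028 and 1.1e-06. Egfr was then 0.54 (limma adjusted p = 0.49) and Tubb2b 0.27 (adjusted p = 0.82), so part of the rise may follow the choroid plexus level. The neural stem cell list was not called (mean -0.07, adjusted p = 0.57, or 0.82 with an estimated correlation). In it Tnc fell, and Hopx, a marker of quiescent stem cells, changed by -0.62 (SE 0.10, adjusted p = 0.016). Sox2 (0.32, adjusted p = 0.28), Nes (0.10, adjusted p = 0.56) and Id3 (-0.33, adjusted p = 0.068) did not pass.

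**Figure D2:**
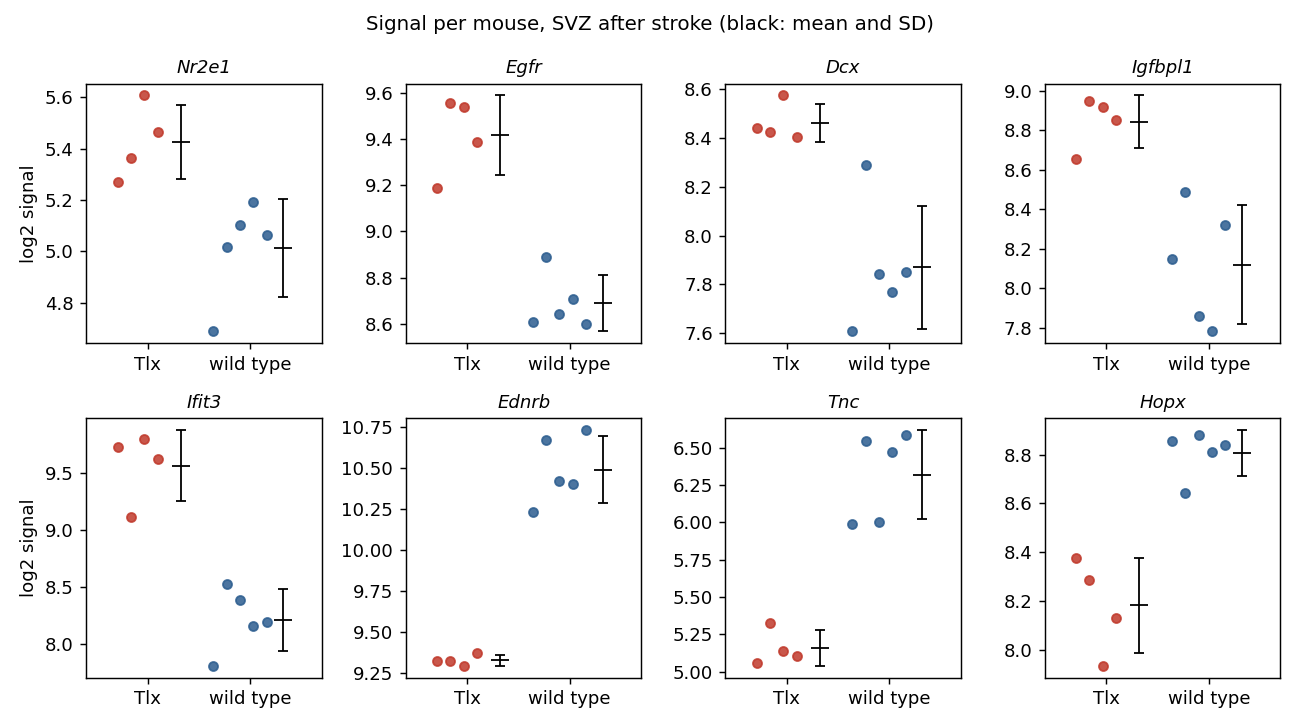
Log2 signal (vertical axes) of 8 genes in each mouse, Tlx overexpressing in red (n = 4) and wild type in blue (n = 5), with the mean and SD in black at the right of each group. Nr2e1, Egfr, Dcx, Igfbpl1 and Ifit3 are higher and Ednrb, Tnc and Hopx lower in every Tlx overexpressing mouse than in every wild type mouse; the Nr2e1 difference (0.41) did not pass the threshold over all probes.

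Genes of the choroid plexus, the secretory epithelium that hangs in the ventricle beside the SVZ, were lower in the Tlx overexpressing mice. All 14 measured genes were negative, with a mean log2 change of -0.72. Calml4 fell (-1.14) and Steap1 fell (-0.83, SE 0.16, adjusted p = 0.037), while Kcne2 (-1.02, adjusted p = 0.064), the klotho gene Kl (-0.94, adjusted p = 0.074) and the transthyretin gene Ttr (-0.34, adjusted p = 0.11) did not pass over all probes. Adjusted over the list alone, all 14 fell. The list was called with the preset correlation (camera adjusted p = 1.7e-10) and not with an estimated correlation (adjusted p = 0.29), and the exact permutation p of its level was 0.016 (0.095 after adjustment). Its level spread widely between mice, from -0.96 in Tlx overexpressing mouse 3155 to 0.62 in wild type mouse c1, with 0.17 in Tlx overexpressing mouse 2995. The difference was 0.0053 among mice 2995, 2989 and 2996 and -0.85 among mice 3155, 3157, 3163 and 3164. Ependymal and motile cilium genes, the neighbouring epithelium, had a mean of -0.11 that did not pass (adjusted p = 0.058, or 0.74 with an estimated correlation). Mia fell there (-0.78, adjusted p = 0.02), and Foxj1 (-0.28, adjusted p = 0.12) did not pass.

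The interferon and antigen presentation list was higher (mean 0.29, 18 of 24 measured genes positive). The members past the threshold were Usp18, Ifit3, Isg15 and Oasl2 (1.21, SE 0.24, adjusted p = 0.037 for its brightest probe), and 9 passed when adjusted over the list alone. That Oasl2 probe was detected in 2 of 5 wild type mice, whose mean of 4.52 lay near background, and did not separate the genotypes, so its change is approximate. The antigen presentation genes went both ways. Psmb8 (0.41, adjusted p = 0.068) and H2-D1 (0.32, adjusted p = 0.18) were among those 9 and did not pass over all probes, and B2m (0.03, adjusted p = 0.92), H2-K1 (0.05, adjusted p = 0.79), Cd74 (-0.42, adjusted p = 0.56) and H2-Ab1 (-0.39, adjusted p = 0.57) passed neither way. The list was called with the preset correlation (camera adjusted p = 8.2e-05) and not with an estimated correlation (adjusted p = 0.36), and its exact permutation p was 0.056. The mean was 0.49 with the range of the mouse number as a block and 0.60 with the choroid plexus level as a covariate. With the covariate, camera at the preset correlation gave an adjusted p of 2.3e-15, and over all settings the adjusted p ran from that to 0.36. The preset of 0.01 treats the genes as nearly independent, whereas camera estimated their correlation at 0.25, so the smallest values overstate the evidence. Its level was 0.40 in Tlx overexpressing mouse 2995 and -0.12 in mouse 3155, within the wild type range of -0.37 to 0.07. Microglia and macrophage genes had a mean of 0.15, with 14 of 19 positive and 0 past the threshold, over all probes or adjusted over the list alone. Cx3cr1 (0.37, adjusted p = 0.092) and C1qb (0.32, adjusted p = 0.14) came closest. This list was called with the preset correlation (adjusted p = 0.011) and not with an estimated correlation (adjusted p = 0.54). Its exact permutation p was 0.071, and it was not called without wild type mouse 3164 (0.10, adjusted p = 0.099) or with the choroid plexus covariate (0.091, adjusted p = 0.23), over a range of adjusted p from 1e-05 to 0.54. Among inflammatory cytokines and chemokines Ccl4 rose by 1.04 (SE 0.13, adjusted p = 0.0052) and Ccl3 did not pass (0.46, adjusted p = 0.099); the list was not called (mean 0.18, adjusted p = 0.12).

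The hypoxia and oxidative phosphorylation lists were lower in the Tlx overexpressing mice. In the hypoxia list 11 of 14 measured genes were negative, with a mean of -0.17. Carbonic anhydrase 9, Car9, changed by -0.68 (SE 0.09, adjusted p = 0.007), and the glycolytic enzyme Pgk1 by -0.44 (SE 0.08, adjusted p = 0.031), although a dimmer Pgk1 probe read 0.08 and another Car9 probe (-0.26) did not pass. Ldha (-0.24, adjusted p = 0.14) and Vegfa (-0.35, adjusted p = 0.17) did not pass, and 5 genes fell when adjusted over the list alone. In the oxidative phosphorylation list 59 of 68 genes were negative, with a mean of -0.17. None passed over all probes on its brightest probe, Ndufb7 being nearest (-0.35, adjusted p = 0.051), and 11 fell when adjusted over the list alone. These lists were called with the preset correlation (camera adjusted p = 0.0036 and 1.8e-09) and not with an estimated correlation (adjusted p = 0.29 for both). Their levels separated the genotypes completely (exact permutation p = 0.0079 for both, 0.095 after adjustment). With the choroid plexus level as a covariate the hypoxia shift was -0.13 (adjusted p = 0.02), that of oxidative phosphorylation was -0.079 (adjusted p = 0.0034, over a range of 2.3e-12 to 0.29), and Cox6b2 turned from -0.58 to 0.02. The oxidative phosphorylation level was -0.16 in mouse 3155 and -0.0059 in mouse 2995, the Tlx overexpressing mice with the lowest and highest choroid plexus level.

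The 4 measured genes reported as repressed by Tlx were all negative, with a mean of -0.42. They were the cell cycle inhibitor Cdkn1a (-0.54, adjusted p = 0.11), Bmp4 (-0.53, adjusted p = 0.20), the astrocyte filament gene Gfap (-0.33, adjusted p = 0.32) and the water channel Aqp4 (-0.27, adjusted p = 0.32). None passed over all probes, and 2 fell when adjusted over the list alone. The list was called with the preset correlation (camera adjusted p = 0.012), not with an estimated correlation (adjusted p = 0.29), not with fry (adjusted p = 0.083) and not with no filter on dim probes (-0.32, adjusted p = 0.21). With the choroid plexus level as a covariate the list stayed called (-0.38, adjusted p = 0.02, over a range of 0.00069 to 0.29), while Bmp4 turned from -0.53 to 0.10. The list's exact permutation p was 0.032 (0.12 after adjustment). In Tlx overexpressing mouse 2995 the level was -0.02, against -0.33 to -0.28 in the other 3. Among wild type mice the level was highest in 2989 (0.492) and 2996 (0.345). It was 0.0783 in c1, 0.113 in c2 and -0.0967 in 3164, so much of the wild type excess lay in mice 2989 and 2996. Over all settings the shift of the list ran from -0.49 to -0.26.

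**Figure D3:**
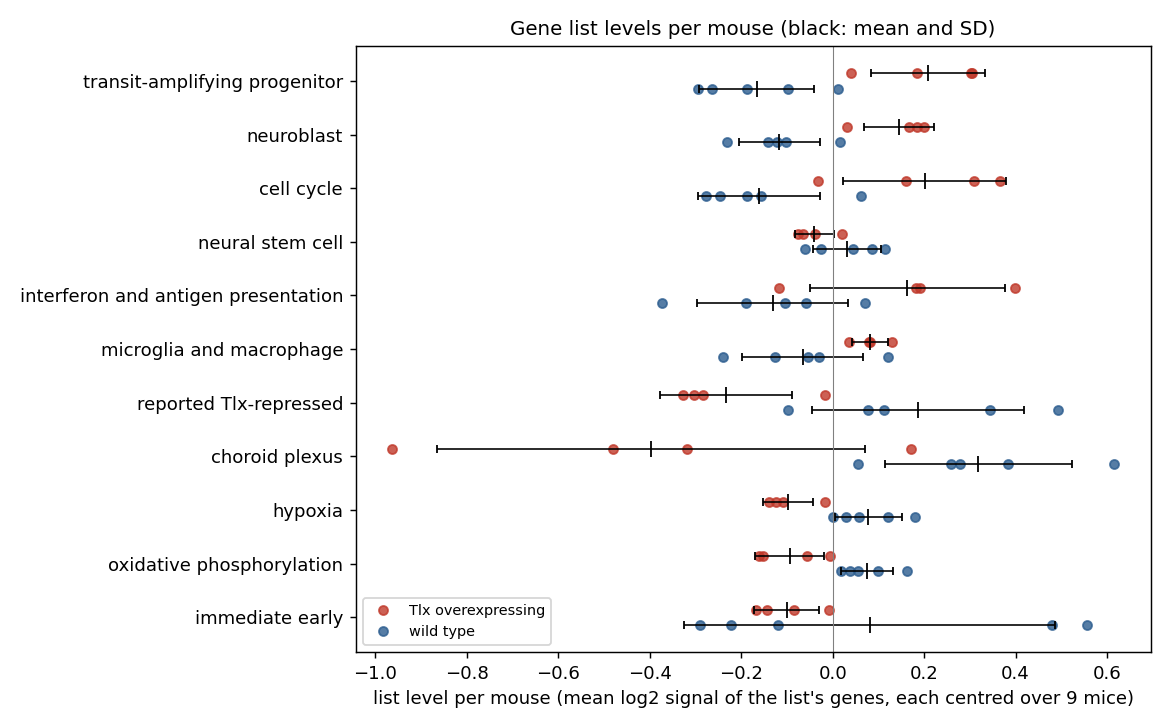
Level of 11 gene lists in each mouse (horizontal axis: mean log2 signal of the list's genes, each gene centred over the 9 mice), Tlx overexpressing in red (n = 4), wild type in blue (n = 5), group mean and SD in black. Transit-amplifying and neuroblast levels are higher and hypoxia and oxidative phosphorylation levels lower in every Tlx overexpressing mouse, and wild type mice 2989 and 2996 lie alone on the right of the immediate early row at 0.56 and 0.48.

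The remaining lists were not called at the preset correlation. Their mean changes were small for astrocytes (-0.03, adjusted p = 0.84), reactive astrocytes (0.10, adjusted p = 0.12), oligodendrocytes (0.07, adjusted p = 0.57), oligodendrocyte precursors (0.10, adjusted p = 0.29), striatal projection neurons (-0.11, adjusted p = 0.058), endothelial cells (-0.13, adjusted p = 0.10) and mural cells and fibroblasts (-0.08, adjusted p = 0.32). Vwf, the von Willebrand factor of endothelium, rose by 0.40 (SE 0.08, adjusted p = 0.038) and Acta2, smooth muscle actin, by 0.85 (SE 0.17, adjusted p = 0.035), both against the sign of their lists. For Acta2, 2 of 4 probes passed and all were positive. Blood genes had a mean of 0.22 (adjusted p = 0.29). Signalling lists gave 0.03 for Wnt (adjusted p = 0.76), -0.0071 for Notch (adjusted p = 0.63), -0.09 for BMP and TGF-beta (adjusted p = 0.12) and -0.03 for Shh (adjusted p = 0.79). Growth factors gave -0.05 (adjusted p = 0.57), ribosomal proteins 0.02 (adjusted p = 0.44) and cell migration genes 0.04 (adjusted p = 0.29). Among the migration genes Prokr2, a receptor needed for neuroblast migration to the olfactory bulb, rose by 0.73 (SE 0.13, adjusted p = 0.029). Cell cycle inhibitors had a mean of -0.0056 and a median of -0.02, while their test pointed up (adjusted p = 0.79); within them Cdkn1b read 0.59 (adjusted p = 0.084) and Cdkn1a -0.54.

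The mature neuron list was not called, with a mean of 0.22 and a median of 0.03 (adjusted p = 0.44). Slc17a6, the vesicular glutamate transporter with the smallest p on the list, read 1.13 (SE 0.38, adjusted p = 0.15), and its other probe read 1.14. The level of Slc17a7, the vesicular glutamate transporter of cortical neurons, ran from 4.97 to 10.37 in wild type mice and from 7.88 to 9.50 in Tlx overexpressing mice. Immediate early genes, which respond to neuronal activity and tissue handling, had a mean of -0.18 (adjusted p = 0.29), and their list level was 0.56 and 0.48 in wild type mice 2989 and 2996 against -0.29 to -0.12 in the other wild type mice. Mice 2989 and 2996 also lay apart on the second principal component, at -18.9 and -18.2, where the other wild type mice lay at 13.3 to 20.5 and the Tlx overexpressing mice at -9.32 to 2.90.

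The repeat arrays of wild type mouse c1 differed less than any pair of mice. The SD of the log2 difference over 20401 probes was 0.167 between its 2 arrays, with 0 probes 2-fold apart and Pearson's r of 0.9965 across probes, which are not independent replicates. Between wild type mice it was 0.213 to 0.332 over 10 pairs, and between Tlx overexpressing mice 0.189 to 0.292 over 6 pairs. A pair of mice of different genotype differed by 0.220 to 0.408.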

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

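The counts over other splits of the mice were planned before the results were seen. The tests of dilution, captured tissue, mouse number, choroid plexus, leaving out mice 3155 and c1, cortical neurons and immediate early genes were chosen after the patterns were seen, and those of mouse number and of leaving out 3155 and c1 were revised after their first values. The test of mouse number first asked for a positive difference in each range, then for an exact permutation p under 0.05 within ranges, which the design cannot give, and last for an interval above 0 with the range as a block.

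A rule for isolated mice compared the gap between the most extreme mouse of a genotype and its nearest neighbour with the whole range. It picked 16 of 328 groups, where chance alone gives about 16.4, so no single case stands out. Among lists it picked the reported Tlx-repressed level of -0.0172 in Tlx overexpressing mouse 2995 and the mature neuron level of 0.508 in Tlx overexpressing mouse 3155. In wild type mice it picked the astrocyte level of 0.15 and the striatal projection neuron level of -0.256 in 2989, and the mural and fibroblast level of 0.282 in c1. Among genes of Tlx overexpressing mice it picked log2 signals of 6.56 for Usp18 and 12.8 for Hba-a1 in 3155, 10.8 for Btg1 in 2995 and 4.91 for Sufu in 3163. In wild type mice these were 5.38 for Ccn5 and 6.81 for Trem2 in 2989, 5.13 for Gsn and 6.69 for Strn in 2996, 4.93 for Isg15 and 6.13 for Lhfpl3 in 3164, and 6.25 for S100a8 in c1.

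For the number of called probes, chance assignment of mice is unlikely. Of 100 splits of the 9 mice drawn at random, the real one included, 1 gave as many as 192, and the highest other split gave 22. These splits ignore the range of the mouse number, and with the range as a block the real count was 51. For the number of called lists chance cannot be excluded: 36 of 100 splits gave at least 9 lists at the preset correlation, with up to 15 in another split and a median of 7. Genes of a list that vary together between mice may be called as a list under many groupings, and the count of 9 lists carries little weight.

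Transit-amplifying, neuroblast and cell cycle lists were higher in the Tlx overexpressing mice. Less choroid plexus tissue, raising all other cells alike, is not settled. The 3 lists exceeded 5 lists of other cells by 0.39 (exact permutation p = 0.0079). Those 5 differed by -0.06 on average, but they were chosen after their values were seen. Cell lists left out went both ways: microglia 0.15, oligodendrocyte precursor 0.10, reactive astrocyte 0.10, mature neuron 0.22 and blood 0.22, but mural and fibroblast -0.08 and neural stem cell -0.07. With the choroid plexus level as a covariate the 3 lists shifted by 0.28, 0.19 and 0.26 against 0.37, 0.26 and 0.36. Part of their rise may follow the choroid plexus level. More SVZ tissue in the captures is not settled either. The 3 lists exceeded the stem cell and ependymal lists by 0.42 (exact permutation p = 0.0079). The mean of the stem cell and ependymal lists itself differed by -0.091 (exact permutation p = 0.04). Both were known to be lower when the test was chosen, and the ependymal list turned to 0.069 with the covariate. The range of the mouse number as the whole cause is not settled, although the difference stayed with it as a block. It was then 0.34 (95% interval of a linear model 0.14 to 0.54) against 0.33 without. That estimate rests on 1 Tlx overexpressing against 2 wild type mice and on 3 against 1, as the range of c1 and c2 holds no Tlx overexpressing mouse. The 12 arrangements within ranges allow no exact permutation p under 0.083. An effect of Tlx on progenitor division or number stays open as a hypothesis and was not tested, nor told apart from expression per cell.

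The choroid plexus list was lower in the Tlx overexpressing mice. A varying amount of choroid plexus tissue in the captures is a candidate explanation: after removing genotype means, the list's 14 genes correlated over mice with a mean of 0.72, above all 10000 random lists of like signal (median -0.0048, 95th percentile 0.085). Other lists also hold genes that vary together. The correlation estimated by camera was 0.61 for oligodendrocytes, 0.60 for striatal neurons and 0.49 for cell cycle and mature neurons, down to -0.045 for Shh signalling. Exceeding random lists therefore does not tell tissue amount from a joint change of expression. Without the mice with the lowest and highest levels, 3155 and c1, the shift was -0.45 (exact permutation p = 0.057 over 35 splits of the other 7), but these mice were picked for their levels, which must shrink the shift, so this value decides nothing. Among the 80 lower probes outside the list, the median correlation with the choroid plexus level within genotypes was 0.46, and 47.5% exceeded 0.5 against 14.3% of all tested probes, while the median was -0.26 among the 110 higher probes, of which 26.4% lay under -0.5 against 12.8% of all, so part of the lower and of the higher genes may follow the choroid plexus level. A lower expression of choroid plexus genes through genotype was not tested apart from tissue amount, as the captures hold both.

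Wild type mice 2989 and 2996 stood apart from the other wild type mice. More cortical excitatory neurons in their captures is a candidate explanation: both mice exceeded each of the other 3 in a list of 9 measured cortical genes, by at least 1.5, and 3 of those genes also stand in the mature neuron list. The cortical level was 0.88 in both 2989 and 2996, -0.92 in c1, -0.85 in c2 and -0.62 in 3164. The Tlx overexpressing mice lay between, at -0.25 to 0.76, so this level varied across all mice. The second principal component ranked the mice in the reverse order, apart from the tie of 2989 and 2996. Between genotypes the cortical level differed by 0.29 (exact permutation p = 0.62). Over the 9 mice Slc30a3 ran from 4.54 to 8.87 and Cck from 5.15 to 9.5. The abundant Camk2a, which striatal neurons express as well, ran only from 10.4 to 11. Immediate early genes were higher in 2989 and 2996 too, by at least 0.6 over the other 3 wild type mice. Tlx overexpressing mouse 3155, with a cortical level of 0.76, had an immediate early level of -0.17. No biological explanation was tested, since the design names none for these 2 mice.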

How the results depend on the processing

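The settings that left out mice 2989 and 2996, left out 3155 and c1, or used the choroid plexus level as a covariate were chosen after the results were seen; all others were set before. The count of 192 called probes stayed within 1.5 times under 7 settings of processing (129 to 236) and was 57 with no filter on dim probes, 98 without c1 and c2, 609 with array weights, 51 with the mouse number range as a block, 107 with a 1.5-fold minimum, 705 at an adjusted p under 0.10, 378 without 2989 and 2996, 6 with the choroid plexus covariate and 31 without 3155 and c1. Leaving out each mouse gave 27 to 753: 753 without 2995, 71 without 3155, 27 without 3157, 39 without 3163, 63 without c1, 84 without 2996, 122 without 3164, and within 1.5 times for c2 and 2989. The cause was not tested, apart from the threshold in the 2 settings that changed it. All 192 probes kept their sign wherever they were tested. The share of higher calls was 110 of 192, 73 of 98 without c1 and c2, 39 of 51 with the block and 286 of 753 without Tlx overexpressing mouse 2995; median scaling gave 82 of 155. The Nr2e1 difference was positive throughout. It passed with array weights (0.474, adjusted p = 0.035), at the looser threshold (0.413) and without 2989 and 2996 (0.504, adjusted p just under 0.05), over a range of adjusted p from 0.035 to 0.88. With the covariate it was 0.243 (SE 0.16) against 0.413 (SE 0.11). The filter requiring all 9 mice gave no value for it.

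The count of 9 lists was 0 with an estimated correlation (3 at an unadjusted p under 0.05), 5 with fry, 17 without 2989 and 2996, 14 with the covariate, and 8 to 14 leaving out each mouse. The fry test asks only whether a list's genes move on balance, and its calls were the transit-amplifying, neuroblast, cell cycle, hypoxia and oxidative phosphorylation lists. The repeat arrays of c1 differed by 0.126 to 0.133 under 3 other settings. Over 3219 alternative values for 135 gene results, 2803 stayed on their side, 304 lost and 89 gained a call and 23 changed sign. Over 749 values of 30 lists these were 659, 16, 48 and 26. Only a result called in the main fit can lose a call, so all 304 losses fell on the 40 called probes and all 16 on the 9 called lists. The 2803 and 659 include results that were never called, so they do not measure how stable the calls were. Of the 40 called probes that the naming rule gave, that of Ednrb alone kept its call in all 24 of its settings, 14 kept it with the block and 3 with the covariate. Called genes named outside the rule were not followed over settings. Ifit3, Fzd10os, Ccl4, C4a, Tnc and Slc25a18 lost theirs with the covariate alone, at changes of 1.51, 0.83, 0.88, 0.87, -1.32 and -0.95 against 1.35, 1.05, 1.04, 1.01, -1.16 and -0.92 and with larger SEs, so these losses do not show that the genes follow the choroid plexus level.

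Signs that changed were of results not called before, and for lists the sign is that of the camera test, which can differ from that of the mean. With the covariate they were Bmp4 0.102, Bcas1 -0.201, Syn2 -0.0275, Slc17a7 -1.2, Lum 0.504, Smo 0.258, Cxcl16 0.114, Igf2 0.132, Dab1 -0.000341 and Cox6b2 0.0179, and the lists ependymal 0.069, oligodendrocyte -0.15 (adjusted p = 0.02), oligodendrocyte precursor -0.077, mature neuron -0.32 (adjusted p = 0.0028), endothelial 0.033 and mural 0.17 (adjusted p = 0.02). Without 2989 and 2996 they were Nefm 0.131, Arc 0.0234, Uty 0.0431, Wnt list -0.014, immediate early list 0.11 (adjusted p = 0.039) and growth factor list 0.0088. Without c1 and c2 they were Slc17a7 -0.472, Smo 0.0034, mature neuron list -0.068 and Notch list 0.028. With the block they were Smo 0.0476 and lists mature neuron 0.036 and mural 0.05. Without 3155 and c1 they were Smo 0.0495 and lists oligodendrocyte 0.0065, mature neuron -0.036 and mural 0.028. With median scaling they were Uty 0.00909 and astrocyte list 0.023, with the first array of c1 Uty 0.00302, and with all probes lists astrocyte 0.011, mural 0.019 and Notch 0.036.

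Leaving out each mouse, the range was -0.00924 to 0.154 for Alas2, -0.186 to 0.00957 for Smo, -0.0781 to 0.0762 for Uty, -0.034 to 0.023 for cell cycle inhibitor, -0.044 to 0.0041 for astrocyte, 0.017 to 0.17 for oligodendrocyte, 0.09 to 0.36 for mature neuron and -0.27 to -0.057 for immediate early. The causes of these changes were not tested. A slide block was not run because no slide is named. A sex covariate was not run because the sex markers, close to background, showed no clear difference between mice. No paired analysis was possible because the mouse numbers of the 2 genotypes pair no animals. Signal over background limits the dim genes: Nr2e1 had a detection p-value of 0.021 on the array of mouse c1 with the larger value, and 2.08% of simulated 1.3-fold changes were called.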

Other observations

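All tests here were chosen after the results were seen, and 2 of them were made stricter after their first values: that of position, by leaving out Gbx2 and Dmrt3, and that of antigen presentation, which had counted any value below 0 as an exclusion.

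Further called genes outside the lists were chosen after their values were seen. They belong to no group that was fixed or tested, and they were not followed over other settings. Higher in the Tlx overexpressing mice were Fbln2 (0.82), Gdf10 (0.73), Draxin (0.72), Elavl4 (0.68, its other probe 0.02), Entpd2 (0.67), Pbk (0.63), Dpysl3 (0.62), Igsf9 (0.62), Insm1 (0.62), Dpysl5 (0.55), Mfge8 (0.55 and 0.51), Esco2 (0.54), Kif18b (0.54), Pbx3 (0.50), Ncaph (0.49) and Sox12 (0.34). Lower were Etnppl (-0.80 and -0.61), Col17a1 (-0.78), Itgb6 (-0.74, its other probe -0.05), Slc14a1 (-0.73), Cldn10 on 3 probes (-0.71, -0.67 and -0.63), Mgst1 (-0.69), Acox2 (-0.68), Plat (-0.65), Pdk4 (-0.65), Aifm3 (-0.61), Fam107a (-0.58), Scrg1 (-0.47), Ephx2 (-0.44) and Gpm6a (-0.40, its other probe 0.13). Other probes of Kif18b, Ncaph, Pbx3, Sox12, Slc14a1, Mgst1 and Col17a1 had the sign of the called probe and did not pass.

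Gbx2, a gene of ventral forebrain, rose and Dmrt3, a gene of the pallium, fell. A more ventral or septal position of the captures is a candidate explanation. The ventral list was higher by 0.27 (exact permutation p = 0.048) and the dorsal list differed by -0.22 (exact permutation p = 0.016). In the ventral and septal list 6 of 9 genes were positive, and Zic1 (-0.12), Zic2 (-0.05) and Zic4 (-0.30) were negative. In the dorsal list 4 of 5 were negative, and Neurog2 (0.28) was positive. Both lists were chosen after Gbx2 and Dmrt3 were seen, and each holds its gene of the 2. Without them the ventral list differed by 0.12 (exact permutation p = 0.3) and the dorsal list by -0.054 (exact permutation p = 0.52). The ventral minus dorsal level then differed by 0.18 (exact permutation p = 0.38), so a shift in position beyond these 2 genes was neither shown nor excluded. With the choroid plexus level as a covariate Dmrt3 went from -0.91 (SE 0.18) to -0.27 (SE 0.14) and Gbx2 from 1.49 (SE 0.31) to 0.93 (SE 0.44), neither then past the threshold, so Dmrt3 in particular may follow the choroid plexus level instead.

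Ednrb, Tnc, Hopx and Slc25a18 fell, and fewer quiescent stem cells, or less of their genes, may underlie this. A list of 12 other measured genes of such cells, 8 of them also in other lists, differed by -0.058 (exact permutation p = 0.40). This leaves the question open, since a p of this size does not show that the levels were alike.

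Usp18, Ifit3, Isg15 and Oasl2 were among the highest genes. A list of 13 measured interferon-stimulated genes, all from the fixed interferon and antigen presentation list and chosen after these 4 were seen, differed by 0.57. Without the 4 genes, 8 of the other 9 were positive and their level differed by 0.23 (exact permutation p = 0.087). Bst2 (0.44), Ifit2 (0.42) and Irf9 (0.34) were the highest of these, and Ifi27 (-0.043) was negative. Taking out the genes that passed leaves only genes that did not, which pulls this difference down. The value therefore decides neither for nor against a wider interferon response. An antigen presentation response may go along with the 4 genes: the list of MHC and antigen processing genes differed by -0.026 (exact permutation p = 0.82), with 6 genes positive and 5 negative, which leaves the question open.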
